A study of Homo sapiens with 9 samples.

How the data were processed

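RNA of HepG2 cells was sequenced in 9 libraries, 3 each from cells given 50 µM PQY09, 50 µM PQY23_1 or 0.1% DMSO, per the labels. Per the submitters' processing notes, which name tools without their roles, cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, edgeR and DESeq2 were used with the genome build hg38. The annotation release, read length, strand setting and exposure time, and whether the compound wells also held DMSO, are not given in the sources used here. Nothing states that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples.

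The authors deposited a single file of 60612 genes with 2 values per gene and library. The deposited estimated counts (expected counts) are whole numbers, and their low values pile up at 4 (10696 cells, against 4024 at 3 and 2277 at 5), with 5956 cells at 1 and 4729 at 2. The number of counts per sequenced fragment is not given; 4 was taken for the floor below and for an alternative. The deposited FPKM values, fragments scaled by gene length and library size by the authors, hold 1e-04 wherever the count is 0 (100% of such cells). Within a library counts and FPKM followed each other over genes, and no column fitted another library better than its own. A count above 0 in any library was found for 31442 genes.

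The counts were used as deposited and rounded to whole numbers. A limma test on log2(FPKM + 1) had been planned before the data were examined, with the rule that a quasi-likelihood count test takes its place if the table holds whole-number counts, which it did. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 20157, and libraries were scaled by TMM (factors 0.977 to 1.026). All 9 libraries were fitted at once in edgeR 4.0.16 with a mean per group and no covariate, which leaves 6 residual degrees of freedom, and the 3 contrasts were tested with the quasi-likelihood F test. P-values were adjusted by Benjamini-Hochberg within a contrast, and a gene was called at an adjusted p below 0.05. The SE of a log2 fold change is its size divided by the square root of F, and intervals are 95%. Intervals and floors cover counting error only as far as counts stand for separate molecules. A gene at 0 in every library of a group was set to a floor of 3 fragments over the group, taken as 12 counts. Coordinates are those of the file (hg38, from 1).

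Gene lists (40, with 817 members tested) were fixed before the data were examined, and so were the groups, the tests, the rule for named genes and most alternatives. Lists with at least 5 members tested were compared with the other genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 40 lists of a contrast. Calls were repeated with a correlation estimated from the data and with fry. Members are counted among all genes tested and "adjusted over the list alone". Named genes are, per contrast, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap and whose higher group has at least 5 CPM, without unnamed or noncoding symbols, then called list members, and a panel of genes fixed in advance. For the contrast between compounds, genes called in opposite directions were added. GO and KEGG terms with 10 to 500 members in the background were tested by a one-sided hypergeometric test against the tested genes that carry a term (2230 GO terms on 11937 genes, 309 KEGG terms on 5585).

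On simulated counts with the fitted spread (common biological coefficient of variation 29.7%), the test recovered 20.9% of genes changed 1.5-fold under PQY09, 70.1% of those changed 2-fold and 100% of those changed 4-fold, and 2.1% of 143 calls were false. Under PQY23_1 the shares were 22.4%, 79.1% and 97%, and 3.65% of 137 calls were false. The genes changed by these folds were drawn from those with a mean of at least 5 CPM, so recovery at lower levels was not simulated. A list raised 1.5-fold in the simulated PQY09 libraries was found. The overlap of the changes under both compounds was set beside 20 simulations of unchanged groups that share their controls. After the results were seen, 20 more simulations were added in which each compound changed its called genes. There the PQY23_1 change of the 173 genes called the same way under both was moved to uncalled genes of similar level. These gave 157 to 217 calls under PQY09 and 105 to 142 under PQY23_1, fewer than in the data, so that genes were also taken by lowest p up to the number called. Alternatives changed the filter, scaling, variance model, threshold, tool and samples, and each library was left out in turn. Those on FPKM, TPM or quantile-normalized FPKM, with a pseudocount, replaced the scaling, the filter and, for genes, the test together: they used limma on the 11646 genes with at least 1 FPKM in 3 libraries. Calculations used R 4.3.3 and DESeq2 1.42.0, with the seed 20261201. No library was left out of the main comparisons.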

Results

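HepG2, a human liver cancer cell line that keeps many hepatocyte functions, was exposed to 50 µM PQY09, to 50 µM PQY23_1 or to 0.1% DMSO, the solvent control, and RNA was sequenced from 3 libraries per group, 9 in all. The series title names PQY09 as Butyrolactone I, a fungal metabolite known as an inhibitor of cyclin dependent kinases, and PQY23_1 as a derivative, and gives the search for targets of these butenolide compounds as the purpose. No structure of PQY23_1 and no exposure time were given in the sources used here. The deposited counts summed to 87122734, 107538450 and 105857549 in the DMSO libraries, to 95622119, 96358372 and 105708329 in the PQY09 libraries and to 100153246, 85050531 and 94643280 in the PQY23_1 libraries. Low counts piled up at 4, and 23192 to 24256 genes had a count above 0. Expression values are counts scaled to library size (CPM) with the SD of 3 libraries, and log2 fold changes with their SE.

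Mitochondrially encoded genes took 13.4% ± 0.755 (SD, n = 3) of the counts under DMSO, 13.3% ± 1.12 under PQY09 and 15.8% ± 1.1 under PQY23_1. The difference between PQY23_1 and DMSO was 2.37 percentage points (two-sided exact permutation p = 0.1, the smallest that 3 libraries against 3 can give), and that between PQY23_1 and PQY09 was 2.43 points (exact permutation p = 0.2). Across genes, which are not independent replicates, Pearson's r between libraries was 0.9674 to 0.9751 within groups and 0.9566 to 0.9715 between groups.

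PQY09 against DMSO asks which transcripts the parent compound changed. Genes of cholesterol synthesis rose together. LSS, which makes lanosterol, rose 2.07-fold, from 124 ± 0.467 to 257 ± 15.2 CPM (SD, n = 3 per group). Genes of fatty acid synthesis rose as well, led by ACSS2, which makes acetyl-CoA from acetate and rose 3.12-fold, from 85.4 ± 3.75 to 266 ± 7.62 CPM. The immediate early gene JUN, a subunit of the AP-1 transcription factor, rose 5.34-fold, from 47.4 ± 2.39 to 253 ± 19.4 CPM, while SLC7A11, the cystine transporter, was 2.53-fold lower, at 35.1 ± 1.44 against 88.8 ± 12.9 CPM.

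In the edgeR quasi-likelihood test of 20157 genes, 574 changed under PQY09 at a Benjamini-Hochberg adjusted p below 0.05, 358 higher and 216 lower, with a median absolute log2 change of 0.577. Of these, 113 moved at least 2-fold, 79 higher and 34 lower. The 3 libraries of each group did not overlap for 24.4% of the genes tested, where chance gives 10%. The count fell to 309, 235 and 289 genes without DMSO replicate 1, 2 or 3, and to 263, 307 and 278 without PQY09 replicate 1, 2 or 3.

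Of the 26 cholesterol genes measured, 19 rose under PQY09, none fell, and all 26 had a fold change above 0 (median log2 0.82; camera adjusted p = 8.26e-31). Adjusted over the list alone, 22 rose and 0 fell, and the call held with an estimated correlation (adjusted p = 0.00382). The calls of 13 of the 19 were kept whichever library was left out. Among these were the decarboxylase MVD (log2 1.22 ± 0.07, adjusted p = 0.00018), LSS (1.05 ± 0.06, 0.00018; chromosome 21, 46188141 to 46228822), the squalene epoxidase SQLE (0.75 ± 0.05, 0.00018) and the sterol methyl oxidase MSMO1 (1.06 ± 0.09, 0.00048). INSIG1, a sterol sensor, was too low to read, at 0.416 ± 0.309 CPM under PQY09 and 0.295 ± 0.144 CPM under DMSO. The GO term for cholesterol synthesis held 15 of its 26 genes among those called higher, against 0.58 expected (hypergeometric adjusted p = 1.5e-15).

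Fatty acid and triglyceride synthesis followed, with 12 of 22 members higher and none lower (median log2 0.61; camera adjusted p = 9.43e-15, and 0.0344 with an estimated correlation). Adjusted over the list alone, 15 rose and 2 fell. ACSS2 (log2 1.64 ± 0.06, adjusted p = 1.2e-05; chromosome 20, 34872146 to 34927962, overlapping GGT7), the elongase ELOVL6 (1.01 ± 0.06, 0.00018), the desaturases FADS2 (1.03 ± 0.07, 0.00026) and SCD (0.64 ± 0.04, 0.00028) and the citrate lyase ACLY (0.82 ± 0.06, 0.00036) were kept in every leave-out. SREBF1, which encodes a transcription factor of these genes, stood at -0.22 ± 0.08 (adjusted p = 0.21). The list of PPARA targets and fatty acid oxidation moved up less (median log2 0.16; camera adjusted p = 0.000169, and adjusted p = 0.086 with an estimated correlation), with 5 of 23 members higher and 1 lower. FABP1, the liver fatty acid binding protein, rose by a log2 of 0.97 ± 0.06 (adjusted p = 0.00024), and the lipid droplet protein PLIN2 fell by 0.54 ± 0.05 (adjusted p = 0.0015).

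**Figure D1:**
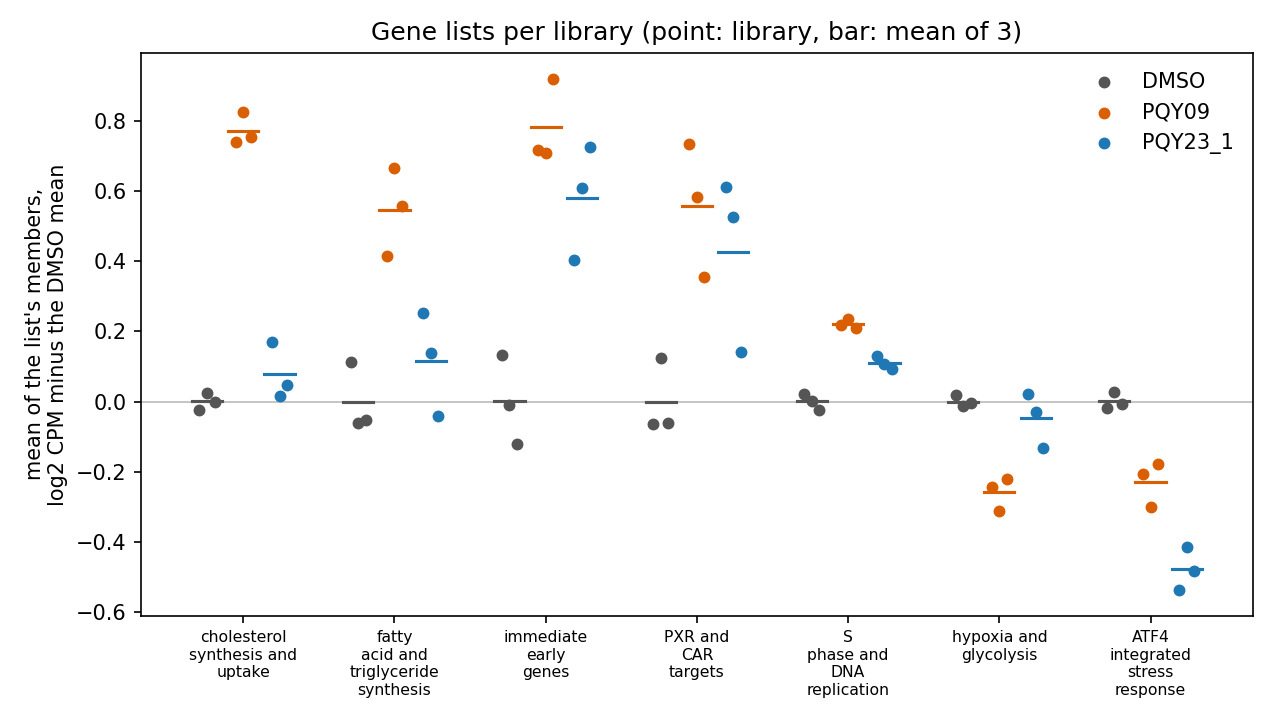
Mean over the members of 7 gene lists in each library, as log2 CPM minus the DMSO mean, with a point per library and a bar at the mean of 3. The cholesterol list sat at 0.74, 0.82 and 0.75 in the PQY09 libraries and at 0.17, 0.02 and 0.05 under PQY23_1. On log2(TPM + 1) its median under PQY23_1 was -0.03, above the median of all genes. The ATF4 list was lower in each library of both compounds than in any DMSO library.

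Immediate early genes rose under PQY09, with 10 of 30 members higher and 1 lower (median log2 0.47; camera adjusted p = 2.91e-05, but adjusted p = 0.133 with an estimated correlation). Adjusted over the list alone, 10 rose and 3 fell. JUN (log2 2.42 ± 0.11, adjusted p = 8.1e-05; chromosome 1, 58780791 to 58784047), FOS, the AP-1 partner of JUN (2.36 ± 0.34, 0.0089), the zinc finger factor EGR1 (2.06 ± 0.2, 0.0013) and the phosphatase DUSP1 (1.97 ± 0.15, 0.00036) were higher, and ETV4, an ETS factor, was lower (-0.74 ± 0.05, 0.00031). Targets of the xenobiotic receptors PXR and CAR rose (6 of 13, none lower; median log2 0.44; camera adjusted p = 1.63e-07, and 0.0204 with an estimated correlation), with 7 higher and 0 lower adjusted over the list alone. They included the cytochromes CYP3A5 (1.11 ± 0.08, 0.00031) and CYP3A7 (1.48 ± 0.17, 0.0034) and the glutathione transferase GSTA2 (1.02 ± 0.07, 0.00031), each a member of a family of similar genes that can share reads. The list member CYP3A4 was tested and was not called under either compound. The iron list (4 of 15 higher, none lower; median log2 0.157; camera adjusted p = 0.000285, and 0.037 with an estimated correlation) and the acute phase list (4 of 14 higher, none lower; median log2 0.155; 0.000195 and 0.0366) shared HAMP, the iron hormone hepcidin, which rose from 19.1 ± 1.13 to 64.3 ± 8.84 CPM (3.36-fold).

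Genes of the ATF4 integrated stress response, many of which serve amino acid import and synthesis, fell under PQY09. Of 31 members, 11 were lower and 2 higher (median log2 -0.18; camera adjusted p = 1.63e-07, and 0.0346 with an estimated correlation). Adjusted over the list alone, 14 fell and 4 rose. The 2 called higher were PPP1R15A (log2 0.53, edgeR adjusted p = 0.016) and ATF3. Their calls were lost in 4 and 2 of the 9 leave-outs. SLC7A11 (log2 -1.34 ± 0.1, adjusted p = 4e-04; chromosome 4, 138164097 to 138242349), the cystathionine lyase CTH (-0.85 ± 0.08, 0.0011), the arginine transporter SLC7A1 (-0.62 ± 0.08, 0.0041) and the glycyl-tRNA synthetase GARS1 (-0.50 ± 0.06, 0.0034) were kept in every leave-out. DDIT3, a stress-induced transcription factor, stood at 0.09 ± 0.21 (adjusted p = 0.9), and TRIB3 at -0.13 ± 0.08 (0.54). Of the 40 tested genes with aminoacyl-tRNA ligase activity, 7 were called lower, against 0.53 expected (hypergeometric adjusted p = 0.00081). The hypoxia and glycolysis list was lower (5 of 30 down, 2 up; median log2 -0.23; camera adjusted p = 0.000147, but adjusted p = 0.0638 with an estimated correlation), with the glucose transporter SLC2A3 at -0.75 ± 0.08 (0.0027). Other falls were in IGFBP1, an insulin-repressed binding protein (2.97-fold lower, adjusted p = 0.00086), TXNIP, a glucose-responsive arrestin (2.32-fold lower, 0.00018), and LYZ, lysozyme (583 ± 85.4 against 1250 ± 213 CPM, 0.0072).

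Butyrolactone I is known to inhibit cyclin dependent kinases, and the values here are mRNA levels of cell cycle genes. Kinase activity and cell cycle phase are not measured by them. The S phase and DNA replication list rose under PQY09 (5 of 30 higher, none lower; median log2 0.21; camera adjusted p = 1.25e-10, and 0.0279 with an estimated correlation), with 15 higher and 0 lower adjusted over the list alone. None of the 5 calls was kept in every leave-out. The lowest p belonged to CHAF1A, a histone chaperone (log2 0.37 ± 0.06, adjusted p = 0.011), which missed the threshold without PQY09 replicate 2 (0.0506). The G2M and mitosis list passed as higher (19 of 28 above 0; median log2 0.09; camera adjusted p = 0.0357, but adjusted p = 0.195 with an estimated correlation). It missed the threshold without DMSO replicate 2 (0.0746), DMSO replicate 3 (0.16), PQY09 replicate 1 (0.0576) or PQY09 replicate 2 (0.0877). Its 1 called member, HMMR, a hyaluronan receptor (log2 0.33 ± 0.06, edgeR adjusted p = 0.018), lost its call without any 1 of the DMSO or PQY09 libraries (highest 0.0862, without DMSO replicate 2). The list of cyclin dependent kinases and cyclins was not past the test (camera adjusted p = 0.263), and of its 29 members only CDKN2B, an inhibitor of CDK4 and CDK6, was called (-0.96 ± 0.13, adjusted p = 0.0061). CDK1 stood at 0.25 ± 0.08 (adjusted p = 0.16), CDK2 at 0.19 ± 0.13 (0.54) and CCNB1, cyclin B1, at 0.00 ± 0.06 (1). The p53 target CDKN1A differed widely between replicates, so that its log2 change of 0.41 had a 95% interval of -1.19 to 2.02.

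Of the 40 lists, 19 passed the camera test under PQY09, 14 higher and 5 lower, and 7 of these held with an estimated correlation: the cholesterol, fatty acid, S phase, ATF4, PXR and CAR, acute phase and iron lists. The sign of the median differed from that of the mean in 8 lists and from that of the test in 4. The NRF2 list and that of amino acid and urea cycle enzymes passed as higher in every leave-out (highest camera adjusted p = 0.00484 and 0.0223). They had 8 and 4 called members. The unfolded protein response, ribosomal protein and ribosome biogenesis lists passed as lower in every leave-out (highest camera adjusted p = 0.00325, 0.00956 and 0.0199). Among the other calls, the list of AHR targets (median log2 0.97, but 0.10 on log2(TPM + 1); camera adjusted p = 0.0357, and adjusted p = 0.18 with an estimated correlation) missed the threshold without DMSO replicate 2 (0.0746) or PQY09 replicate 2 (0.088). The heat shock list (3 of 20 higher; median log2 0.115; 0.00855, and adjusted p = 0.332 with an estimated correlation) missed it without DMSO replicate 2 (0.0633).

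PQY23_1 against DMSO asks the same of the derivative. Genes of amino acid supply and of the ATF4 response fell. SLC7A11 was 2.9-fold lower, at 30.6 ± 1.86 against 88.8 ± 12.9 CPM (SD, n = 3 per group). The asparagine synthetase ASNS was 2.58-fold lower, at 39 ± 5.29 against 100 ± 5.05 CPM, and CTH was 2.36-fold lower. VKORC1L1, a vitamin K epoxide reductase, rose 2.71-fold, from 24.5 ± 1.3 to 66.5 ± 1.03 CPM, and TIMP1, an inhibitor of matrix metalloproteinases, rose 2.65-fold, from 68.3 ± 2.64 to 181 ± 20.2 CPM.

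The edgeR test called 514 of 20157 genes under PQY23_1, 305 higher and 209 lower, with a median absolute log2 change of 0.563. Of these, 85 moved at least 2-fold, 58 higher and 27 lower, and the groups did not overlap for 22.5% of genes (10% by chance). Limma on log2(FPKM + 1) of 11646 genes gave 367 higher and 343 lower with a median log2 change of -0.009 over these genes. After rescaling to equal sums per library (TPM) the same test gave 155 higher and 591 lower with a median of -0.112. Over the 20157 genes, from which the list medians under TPM were taken, the median under TPM was -0.075. A list median above that value lies above the rest even where it is below 0. The count was 260, 138 and 212 without DMSO replicate 1, 2 or 3, 321 without PQY09 replicate 1, and 314, 342 and 220 without PQY23_1 replicate 1, 2 or 3.

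In the ATF4 list 16 of 31 members fell under PQY23_1 and 1 rose, and 27 lay below 0 (median log2 -0.39; camera adjusted p = 3.04e-19). The call held with an estimated correlation (adjusted p = 0.0125), and adjusted over the list alone 21 fell and 2 rose. PPP1R15A was the 1 called higher (log2 0.42, edgeR adjusted p = 0.044), a call lost in 8 of the 9 leave-outs. Among the 11 members kept in every leave-out were CTH (log2 -1.24 ± 0.08, adjusted p = 0.00035), SLC7A11 (-1.54 ± 0.11, 0.00044), PHGDH, the first enzyme of serine synthesis (-0.70 ± 0.06, 0.00088), SLC7A1 (-0.86 ± 0.08, 0.0014), ASNS (-1.37 ± 0.15, 0.004), the mitochondrial folate enzyme MTHFD2 (-0.95 ± 0.12, 0.006) and TRIB3 (-0.58 ± 0.08, 0.01). Again 7 of the 40 tested genes with aminoacyl-tRNA ligase activity were called lower, against 0.48 expected (hypergeometric adjusted p = 0.00068). Outside the list, SLC2A3 fell by 1.22 ± 0.09 (adjusted p = 0.00049), TXNIP by 0.91 ± 0.07 (0.00088), the integrin activator FERMT1 by 1.46 ± 0.2 (0.01) and PLIN2 by 0.64 ± 0.06 (0.0012).

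Higher genes were spread over several lists, whose camera calls were each lost with an estimated correlation. The NRF2 and amino acid lists passed as higher under PQY09 too, and neither passed between the compounds. Immediate early genes rose (7 of 30 higher, 1 lower; median log2 0.354; camera adjusted p = 0.000117, but adjusted p = 0.254 with an estimated correlation), with 13 higher and 2 lower adjusted over the list alone. JUN rose by a log2 of 1.26 ± 0.11 (adjusted p = 0.0012), DUSP1 by 1.53 ± 0.15 (0.0023) and ZFP36, which destabilizes mRNA, by 1.02 ± 0.12 (0.0045). PXR and CAR targets rose (4 of 13, none lower; median log2 0.355; camera adjusted p = 7.58e-05, but adjusted p = 0.0546 with an estimated correlation), among them CYP3A5 (0.88 ± 0.08, 0.0018) and GSTA2 (0.75 ± 0.07, 0.0023). NRF2 targets, the antioxidant genes, rose in 6 of 28 members and fell in 1, SLC7A11 (median log2 0.15; camera adjusted p = 0.000787, but adjusted p = 0.306 with an estimated correlation), with the exporter ABCC3 at 0.64 ± 0.06 (0.0012). Enzymes of amino acid breakdown and the urea cycle rose in 5 of 19 members (median log2 0.13; camera adjusted p = 0.00183, but adjusted p = 0.254 with an estimated correlation), including HPD (0.95 ± 0.06, 0.00035) and FAH (0.65 ± 0.07, 0.0042) of tyrosine breakdown. HAMP rose 2.61-fold (adjusted p = 0.00078), in an acute phase list with 4 of 14 higher (median log2 0.24; camera adjusted p = 0.00129, but adjusted p = 0.117 with an estimated correlation).

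The cholesterol list passed the camera test under PQY23_1 with a median log2 of 0.12, which became -0.03 under TPM (camera adjusted p = 0.00745, but adjusted p = 0.275 with an estimated correlation). The median over all genes under TPM was lower still, so the list stayed above the rest. It had 3 of 26 members higher and none lower, and 5 higher and 2 lower adjusted over the list alone; none of the 3 calls was kept in every leave-out. The fatty acid list (1 of 22 higher, 1 lower; median log2 0.115, or -0.02 under TPM; camera adjusted p = 0.0297, but adjusted p = 0.338 with an estimated correlation) missed the threshold without PQY23_1 replicate 2 (0.129) or 3 (0.0524). ACSS2 rose by a log2 of 0.57 ± 0.05 (adjusted p = 0.0022), while FASN stood at 0.08 ± 0.1 (0.8) and SCD at 0.10 ± 0.04 (0.31).

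Mitochondrially encoded genes, whose share of counts was 2.37 percentage points higher than under DMSO, had a median log2 change of 0.24 (camera adjusted p = 0.000692, but adjusted p = 0.338 with an estimated correlation). EdgeR called 0 of the 13 over all genes, with 6 at an unadjusted p below 0.05 and 2 called by DESeq2; 5 were higher adjusted over the list alone, and the list was lower by camera on quantile-normalized log2(FPKM + 1) (adjusted p = 0.817). The nuclear encoded oxidative phosphorylation list moved with it (median log2 0.08, or -0.05 under TPM; camera adjusted p = 0.0252, but adjusted p = 0.47 with an estimated correlation) and missed the threshold without DMSO replicate 1 (0.0809) or PQY23_1 replicate 1 (0.498). In all 17 lists passed, 14 higher and 3 lower, and only the ATF4 list held with an estimated correlation. The sign of the median differed from that of the mean in 3 of the 40 lists and from that of the test in 5. The S phase and DNA replication list passed under PQY23_1 as well (23 of 30 above 0; median log2 0.11, or -0.02 under TPM; camera adjusted p = 0.00132, but adjusted p = 0.254 with an estimated correlation). Its member CHAF1A was called (log2 0.29 ± 0.06, edgeR adjusted p = 0.033), a call that ended when any 1 of the 9 libraries was left out (highest adjusted p = 0.113, without PQY23_1 replicate 3), and 3 were higher and none lower adjusted over the list alone. The G2M and mitosis list (camera adjusted p = 0.0845) and that of cyclins and cyclin dependent kinases (0.387) were not past the test, with CDK1 at 0.22 ± 0.08 (edgeR adjusted p = 0.23) and CDK2 at 0.26 ± 0.13 (0.36).

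PQY23_1 against PQY09, at the same 50 µM, asks where the responses to the compounds differ. Cholesterol genes were lower under PQY23_1, and so were fatty acid genes, whose list call was lost with an estimated correlation (adjusted p = 0.0544). ACSS2 was 2.1-fold lower (log2 -1.07 ± 0.06, 95% interval -1.20 to -0.94, n = 3 per group), and LSS stood at 153 ± 9.09 CPM against 257 ± 15.2. TIMP1 was 3.53-fold higher under PQY23_1 (log2 1.82 ± 0.09, interval 1.61 to 2.03). UGT1A3, a glucuronosyltransferase that shares exons with UGT1A1 and UGT1A6, was 11.7-fold higher, at 6.18 ± 2.14 against 0.527 ± 0.0407 CPM.

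The edgeR test of the difference called 448 genes, 246 higher and 202 lower under PQY23_1, with a median absolute log2 difference of 0.638. Of these, 111 differed at least 2-fold, 63 higher and 48 lower, and 22% of genes did not overlap (10% by chance). More genes were lower than higher under some other settings. In edgeR 195 were higher and 297 lower with scaling by total counts, and 174 and 227 among genes with a mean of at least 5 FPKM. Limma on 11646 genes gave 243 and 355 on log2(FPKM + 1), and 237 and 330 with 0.1 or 0.01 added. On log2(TPM + 1) limma gave 149 and 794, and the median over these genes was -0.144, against -0.033 on log2(FPKM + 1). Over the 20157 genes, from which list medians were taken, it was -0.102 under TPM. The count fell to 222, 240 and 275 without PQY09 replicate 1, 2 or 3, and to 286 and 268 without PQY23_1 replicate 2 or 3.

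All 26 cholesterol genes were lower under PQY23_1 than under PQY09, 16 of them past the test (median log2 -0.68; camera adjusted p = 2.07e-29, and 0.00436 with an estimated correlation, the one list call of this comparison that held so). Adjusted over the list alone, 22 were lower and none higher. TM7SF2, a sterol reductase, differed by a log2 of -1.02 ± 0.09 (adjusted p = 0.0012), a call kept in every leave-out. LSS differed by -0.75 ± 0.06 (0.00084) and SQLE by -0.63 ± 0.05 (0.00052). SREBF2, the transcription factor gene of this pathway, differed by -0.42 ± 0.05 (0.0061). In the fatty acid list 9 of 22 were lower (median log2 -0.46; camera adjusted p = 9.21e-14, but adjusted p = 0.0544 with an estimated correlation), and 15 were lower adjusted over the list alone. FADS2 differed by -1.01 ± 0.07 (0.00034) and ELOVL6 by -0.74 ± 0.06 (0.00084). FABP1 was 2.26-fold lower under PQY23_1 (adjusted p = 1e-04).

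**Figure D2:**
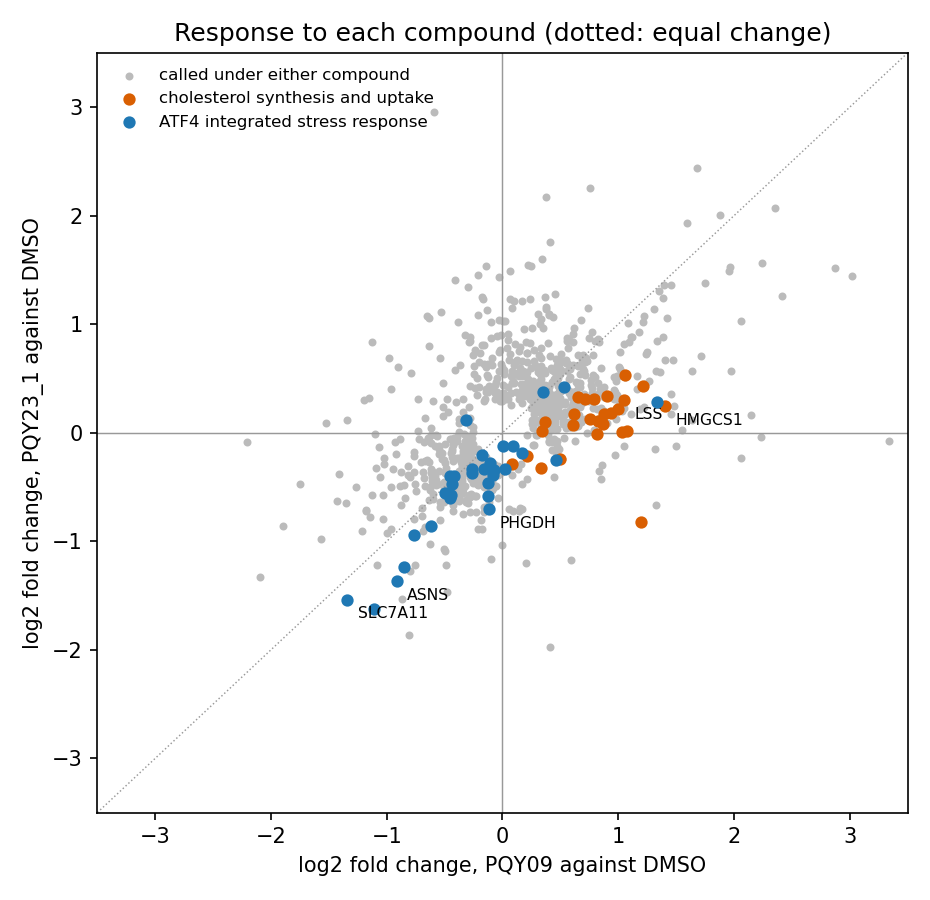
Log2 fold change against DMSO under PQY09 (horizontal axis) and PQY23_1 (vertical axis) for the 890 of 908 genes called under either compound that lie within the axes, with all members of the cholesterol and ATF4 lists marked. Cholesterol genes lie right of the dotted line of equal change (LSS at 1.05 and 0.30), and SLC7A11 and ASNS lie low under both compounds.

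The ATF4 list was lower under PQY23_1 than under PQY09 (7 of 31 lower, none higher; median log2 -0.18; camera adjusted p = 2.87e-08, but adjusted p = 0.0544 with an estimated correlation), with 10 lower adjusted over the list alone. PHGDH differed by -0.58 ± 0.06 (adjusted p = 0.0013) and SLC7A5, a leucine transporter, by -0.34 ± 0.05 (0.0078). The difference for ASNS was -0.45, with an interval of -0.80 to -0.11 (adjusted p = 0.2). Immediate early genes as a list did not pass (camera adjusted p = 0.243), and JUN was lower under PQY23_1 (log2 -1.15, interval -1.40 to -0.91, 0.0012). For the PXR and CAR list (median log2 -0.16; camera adjusted p = 0.0401, but adjusted p = 0.185 with an estimated correlation) the call ended without DMSO replicate 2 (0.0518), PQY09 replicate 1 (0.12), PQY09 replicate 2 (0.0553) or PQY23_1 replicate 3 (0.0958); its member CYP3A7 differed by -1.23 ± 0.17 (0.0086). In the hypoxia list 3 of 30 were higher and 1 lower (median log2 0.165; camera adjusted p = 0.000244, but adjusted p = 0.133 with an estimated correlation), with the phosphofructokinase PFKP at 0.93 ± 0.11 (0.0041).

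Mitochondrially encoded genes were higher under PQY23_1 than under PQY09 as a list (median log2 0.24; camera adjusted p = 5.45e-06, but adjusted p = 0.356 with an estimated correlation; lower on quantile-normalized log2(FPKM + 1), 0.585), beside a share of counts that was 2.43 percentage points higher. The oxidative phosphorylation list (median log2 0.12, or -0.04 under TPM; 0.00033, but adjusted p = 0.407 with an estimated correlation) lost its call without PQY23_1 replicate 1 (0.0894). The ribosomal protein list (median log2 0.12, or -0.04 under TPM; 0.000713, but adjusted p = 0.539 with an estimated correlation) also lost its call without that library (0.305). EdgeR called 0 members of these 3 lists over all genes, against 7, 3 and 6 at an unadjusted p below 0.05 and 1, 0 and 1 called by DESeq2, in the order given. In all, 14 lists passed, 6 higher and 8 lower, and the sign of the median differed from that of the mean in 6 of the 40 and from that of the test in 4.

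The S phase and DNA replication list was lower under PQY23_1 than under PQY09 (26 of 30 below 0; median log2 -0.11; camera adjusted p = 0.000755, but adjusted p = 0.184 with an estimated correlation). EdgeR called 0 of its members over all genes, against 7 at an unadjusted p below 0.05 and 1 called by DESeq2, and 1 was lower adjusted over the list alone. The difference in CDK1 was -0.03 with an interval of -0.22 to 0.15, in CDK2 0.06 (-0.22 to 0.35) and in CYP1A1, a target of the aryl hydrocarbon receptor, -0.12 (-0.67 to 0.42). CDKN2B was higher under PQY23_1 by a log2 of 1.36 ± 0.13 (edgeR adjusted p = 0.0013), in a list of cyclins and cyclin dependent kinases that did not pass (camera adjusted p = 0.794). The gene listed as AC023509, which overlaps PCBP2 and PRR13 on chromosome 12, had 56.4 ± 22.4 CPM under PQY09 and 0 in each other library. With a floor of 12 counts over the group (3 fragments if 4 counts make 1), this is at least 1420-fold above DMSO and at least 1290-fold above PQY23_1. Whether its counts come from reads of the overlapping genes was not tested. Some other genes switched within a group, such as FAM47E-STBD1 at 22.164, 18.467 and 0 CPM in the PQY09 libraries.

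The compounds also had calls against DMSO in common. Of the genes called in both comparisons, 101 were higher under both and 72 were lower under both. Independent calls would give 5.42 and 2.24, without regard to the 3 DMSO libraries that both comparisons share. In 20 simulations with that sharing, in which no gene was changed the same way by both compounds, and with as many genes taken by lowest p as were called in the data, 18 to 31 genes were higher under both and 8 to 20 lower. In the data 173 genes were called the same way under both, and 56 to 124 with a library left out. Of these 173 genes, 20 differed between the compounds by the test of the difference. A condition common to all 3 DMSO libraries would also give genes called the same way under both, and was not tested. HAMP, JUN, DUSP1, CYP3A5 and GSTA2 were among those higher under both, and SLC7A11, CTH, SLC7A1, TXNIP, SLC2A3 and PLIN2 among those lower. Across all genes tested the Pearson r of the fold changes was 0.515, within the 0.456 to 0.526 of 20 simulations of unchanged groups that share controls. The share of genes with the same sign, 67.2%, was also within the simulated 66.1% to 67.4%, while the covariance of 0.279 was above the simulated 0.193 to 0.245. A further 7 genes were called in opposite directions, against 6.98 for independent calls without regard to the shared controls, among them COL2A1, the collagen II chain, and LGALS1, the lectin galectin 1. The call of LGALS1 under PQY09 ended without PQY09 replicate 1 (adjusted p = 0.116, the highest), any DMSO library, the other PQY09 libraries or PQY23_1 replicate 3.

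**Figure D3:**
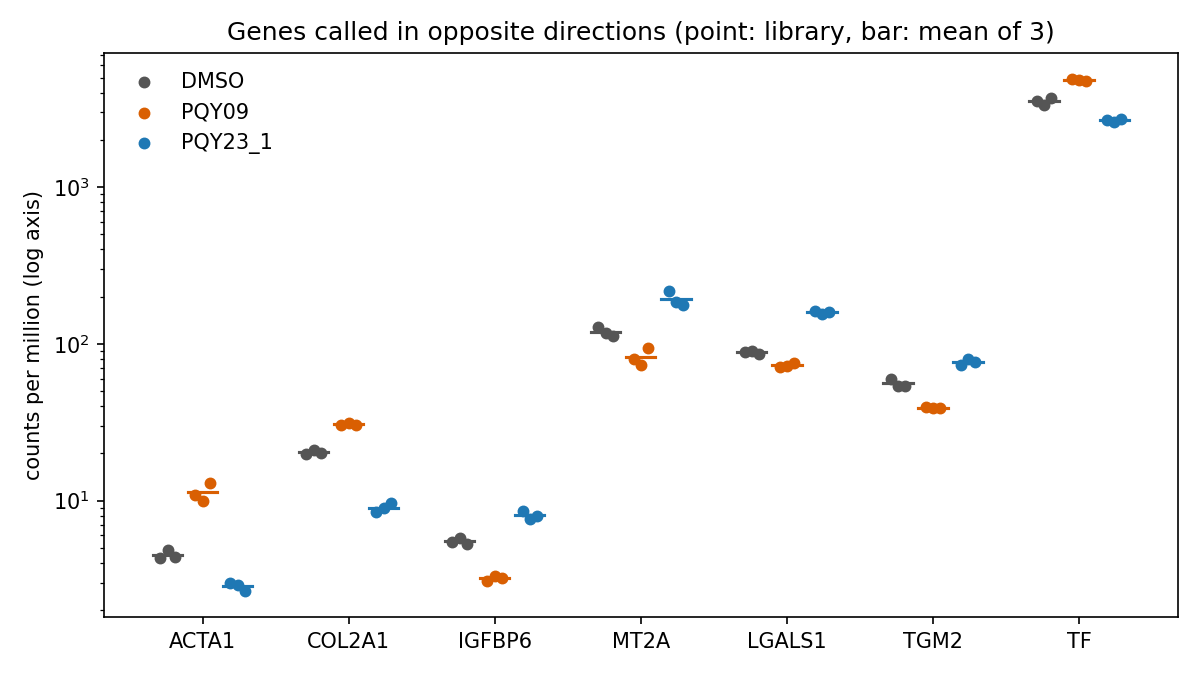
CPM on a log axis of the 7 genes called higher under one compound and lower under the other, with a point per library and a bar at the mean of 3. COL2A1 stood at 30.6 ± 0.417 under PQY09 and 9.02 ± 0.57 under PQY23_1, and LGALS1 at 72.9 ± 1.94 and 159 ± 4.88.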

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

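The tests of scaling and of single libraries below were chosen only after the results were seen; the tests of GC content and length, of single controls and of other splits were not. The following 7 genes are listed because they were called higher under one compound and lower under the other, and the difference itself passed the edgeR test. Opposite calls make a large difference, so its passing follows from the choice and adds no support. Independent calls would give 6.98 such genes, without regard to the shared controls. ACTA1, skeletal muscle actin, had log2 changes of 1.32 under PQY09 and -0.67 under PQY23_1, a difference of -1.99 ± 0.13 (SE, n = 3 per group). Its call under PQY23_1 ended without DMSO replicate 2 (adjusted p = 0.132, the highest) and also without the other DMSO libraries, PQY09 replicate 1 or any PQY23_1 library. COL2A1 stood at 0.59 and -1.17, a difference of -1.76 ± 0.07. IGFBP6, a binding protein of insulin-like growth factors, stood at -0.79 and 0.55, a difference of 1.34 ± 0.1, and its call under PQY23_1 ended when any 1 of the 9 libraries was left out (highest 0.106, without DMSO replicate 3). MT2A, a metallothionein with similar paralogs, stood at -0.54 and 0.69, a difference of 1.23 ± 0.11; its call under PQY09 ended without PQY09 replicate 1 (adjusted p = 0.144, the highest) and also without any DMSO library, PQY09 replicate 2, PQY23_1 replicate 2 or PQY23_1 replicate 3, and that under PQY23_1 ended without DMSO replicate 2 (0.0833) or DMSO replicate 3. LGALS1 stood at -0.28 and 0.85, a difference of 1.12 ± 0.05, and its call under PQY09 ended without PQY09 replicate 1 (0.116, the highest), any DMSO library, the other PQY09 libraries or PQY23_1 replicate 3. TGM2, a transglutaminase, stood at -0.51 and 0.46, a difference of 0.97 ± 0.06; its call under PQY23_1 ended without DMSO replicate 2 (0.0551). TF, the iron carrier transferrin, stood at 0.44 and -0.41, a difference of -0.85 ± 0.05. The calls of COL2A1 and TF against DMSO, and the difference in each of the 7, were kept in every leave-out.

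The cholesterol list was higher under PQY09. As a difference of mean log2 values its median was 0.84 with TMM and at least 0.83 over 5 scalings, TMM included, which argues against scaling between libraries. After each library's trend on GC content and length was removed it was 0.82 ± 0.07, from 0.86 over the same members, which argues against that bias. This SE is over members, which are not independent. The lowest PQY09 library lay 0.57 above the highest of the other 6 libraries in the mean of the list, which argues against a single library as the source. A response of the cells to PQY09 may account for the pattern and stays open as a hypothesis, as do reads shared with pseudogenes of these genes, which were not tested.

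The mitochondrially encoded, oxidative phosphorylation and ribosomal protein lists passed the camera test as higher under PQY23_1 than under PQY09, but none held with an estimated correlation (adjusted p = 0.356, 0.407 and 0.539). On log2(TPM + 1) their medians were 0.09, -0.04 and -0.04 against -0.102 over the 20157 genes. Each list stayed above the rest, but by less than in the main test, where the median over all genes was -0.0089. Camera on quantile-normalized log2(FPKM + 1) kept the oxidative phosphorylation call (adjusted p = 0.0189), lost the ribosomal one (0.114) and put the mitochondrial list lower (0.585). The reasons for these changes were not tested. After removal of the trend on GC content and length their medians were 0.19 ± 0.03 (from 0.25), 0.09 ± 0.02 (from 0.12) and 0.08 ± 0.02 (from 0.12), so that trend is not the whole cause. These SEs are over members, which are not independent. The lowest PQY23_1 library lay -0.05, 0.01 and -0.01 from the highest PQY09 library; no single library ended the mitochondrial call, while the others ended without PQY23_1 replicate 1 (camera adjusted p = 0.0894 and 0.305), which leaves a single library as a candidate source for the ribosomal list and keeps it from being told apart from a shift of the group for the other 2. The ribosomal list also moved under PQY09. Its median against DMSO was -0.09 ± 0.03 under PQY09 and 0.03 ± 0.02 under PQY23_1. Its highest PQY09 library lay 0.07 below its lowest DMSO library, and no library left out ended that call. The call was, however, lost with an estimated correlation. For this list the values argue against a change in the PQY23_1 libraries alone. A response to PQY23_1 or to PQY09 stays open and untested.

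The ATF4 list was lower under both compounds, which share their 3 controls. Against each DMSO library alone, the highest of its medians was -0.17 under PQY09 and -0.4 under PQY23_1 (SE over members 0.08 and 0.1). Each median thus lay below 0, which argues against one control as the source. SEs here are over members, which are not independent, and do not measure the spread between libraries. After removal of the trend on GC content and length the medians were -0.22 ± 0.09 under PQY09 (from -0.18) and -0.43 ± 0.08 under PQY23_1 (from -0.38). A lower ATF4 response to each compound may account for this and remains a hypothesis. The members PPP1R15A, called higher under both compounds, and ATF3, called higher under PQY09, went the other way. A condition common to all 3 DMSO libraries, which may also matter, was not tested.

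Each comparison of 3 libraries against 3 has 10 splits, too few for a share under 0.05. The real split called 574 genes under PQY09, and the highest of the others called 6. Under PQY23_1 the values were 514 and 7, and between the compounds 448 and 6. For lists the real split passed 19, 17 and 14, and the highest others 9, 8 and 7. In each case 1 split, the real one, reached the real value.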

How the results depend on the processing

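On counts simulated at the fitted spread and depth, 20.9% of genes changed 1.5-fold under PQY09 and 100% of those changed 4-fold were recovered. This holds for genes with a mean of at least 5 CPM, and lower levels and other depths were not simulated. Counts simulated with the changes of the called genes gave fewer calls than the data (157 to 217 under PQY09, against 574). Recovery in the libraries themselves may thus differ from these shares. The named genes gave 7151 values under alternatives other than leaving out a library, of which 6277 kept their direction and their side of the threshold, 873 kept the direction only and 1 turned, and 3294 values with a library left out (2273 kept both and 1021 the direction only). For lists these were 348 values (280, 66 and 2 turned) and 450 (418 and 32). All alternatives chosen before the data were seen were run; dividing counts by 4, scaling by total counts, leaving out mitochondrially encoded genes and camera on z-scores were chosen after seeing the data.

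For the changes listed here the cause was not tested, except that stricter thresholds call fewer genes by construction and that leaving out libraries leaves fewer to test on. The count under PQY09 was 342 with the replicate number as a block, 113 at 2-fold, 197 at an adjusted p below 0.01 and 1464 by DESeq2, and 235 to 628 with a library left out. Under PQY23_1 it was 237 with the block, 224 with only the 6 libraries compared, 85 at 2-fold, 120 below 0.01 and 1480 by DESeq2, and 138 to 371 with a library left out. Between the compounds it was 267 with the block, 295 with 6 libraries, 943 by limma on TPM, 111 at 2-fold, 188 below 0.01 and 1285 by DESeq2, and 222 to 397 with a library left out. Lists passing with an estimated correlation numbered 7, 1 and 1, with adjusted p = 0.275 for cholesterol under PQY23_1 and 0.0544 for ATF4 between the compounds, and with a library left out 17 to 22, 13 to 20 and 11 to 15. Genes called the same way under both compounds numbered 282 by limma on quantile-normalized FPKM, 87 with the block, and 56 to 124 with a library left out. On quantile-normalized FPKM the mitochondrial list turned lower (0.817 against DMSO, 0.585 against PQY09) and FTL under PQY23_1 went to 0 (adjusted p = 1). The labels do not state that libraries with the same number belong together, and 2 of 9 libraries correlated best with one of their own number.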

Other observations

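Single members of several other lists were called. The list of NFKB and inflammatory genes passed under neither compound (camera adjusted p = 0.134 and 0.212). Its member ICAM1, an adhesion molecule, fell under PQY09 (log2 -0.76 ± 0.06, SE, n = 3 per group; edgeR adjusted p = 0.00032) and under PQY23_1 (-0.47 ± 0.06, 0.0048). The chemokine CXCL8 rose under PQY23_1 (0.88 ± 0.12, 0.01) and under PQY09 (0.56 ± 0.12, 0.049), where the call ended when any 1 of the 9 libraries was left out (highest adjusted p = 0.151, without PQY09 replicate 3). CCL20, another chemokine, fell under PQY23_1 (-0.77 ± 0.1, 0.0095) and under PQY09 (-0.70 ± 0.1, 0.011), where the call ended without DMSO replicate 2 (0.0522) or PQY09 replicate 3. The lysosome and autophagy list did not pass under PQY09 (camera adjusted p = 0.706) and passed under PQY23_1 (median log2 0.13, or 0.00 under TPM; 0.00931, but adjusted p = 0.306 with an estimated correlation). Its member MAP1LC3B, which coats autophagosomes, rose under both compounds (0.72 ± 0.07 and 0.69 ± 0.07, adjusted p = 0.001 and 0.0023). The sialidase NEU1 rose under PQY09 (0.63 ± 0.06, 0.0012) and stood at 0.23 ± 0.06 under PQY23_1 (0.097). Both inducible HSP70 genes, which differ little in sequence, rose under PQY09 (HSPA1A 0.77 ± 0.06 and HSPA1B 0.80 ± 0.07, both 0.00052) and under PQY23_1 (0.44 ± 0.06, 0.011, and 0.51 ± 0.07, 0.0075). The call of HSPA1A under PQY23_1 ended without DMSO replicate 2 (0.0575). The heat shock list passed under PQY23_1 as well (median log2 0.10, or -0.03 under TPM; camera adjusted p = 0.000256, but adjusted p = 0.306 with an estimated correlation).

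Secreted liver proteins differed between the compounds in both directions. Their list was lower under PQY23_1 than under PQY09, with 7 of 28 lower and 3 higher (median log2 -0.16; camera adjusted p = 0.00531, but adjusted p = 0.215 with an estimated correlation). The lipoprotein gene APOC3 was lower under PQY23_1 (-0.77 ± 0.11, adjusted p = 0.0084) and APOA2 higher (0.55 ± 0.08, 0.0078). The list of biliary and progenitor markers did not pass (camera adjusted p = 0.794), with 8 of 11 members below 0 and a median log2 of -0.21. Its members KRT19 (0.67 ± 0.09, 0.0076) and SOX4 (0.64 ± 0.08, 0.0062) were called higher, and adjusted over the list alone 2 were higher and 3 lower. The IL6 receptor IL6R was higher (0.59 ± 0.07, 0.0035). Of the leukocyte markers (7 tested, 2 higher; median log2 0.52; camera adjusted p = 0.0023, but adjusted p = 0.184 with an estimated correlation), the B cell receptor gene CD79A stood at 3.47 ± 0.137 CPM under PQY23_1 and 1.09 ± 0.282 under PQY09. Among glucuronosyltransferases, which have similar paralogs, UGT2B11 was 3.19-fold higher and UGT2B4 1.51-fold higher under PQY23_1 than under PQY09, and the GO term for UDP-glycosyltransferases held 5 of its 12 genes among those called higher (hypergeometric adjusted p = 0.0013). Against DMSO the term held 4 of 12 among genes called lower under PQY09 (hypergeometric adjusted p = 0.0073). UGT2B4 fell under PQY09 (log2 -0.65 ± 0.07, edgeR adjusted p = 0.0018) and stood at -0.05 ± 0.07 under PQY23_1 (0.8). UGT2B11 fell under PQY09 (-0.98 ± 0.21, 0.044) and stood at 0.69 ± 0.2 under PQY23_1 (0.13). Its call under PQY09 ended without PQY09 replicate 1 (0.146, the highest) and without each other library except DMSO replicate 2. UGT2B7, also lower under PQY09 (edgeR adjusted p = 0.035), lost its call in 6 of 9 leave-outs (highest 0.129, without DMSO replicate 2). The calls of UGT2B4 and UGT2B10 were kept in each.

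Within groups, 157 of 10848 genes with a mean of at least 5 CPM differed at least 2-fold between the highest and lowest of the 3 libraries in all 3 groups. CDKN1A was among them, at 67.3 ± 40.2 CPM (SD) under DMSO and 89.6 ± 49.1 under PQY09. The principal components of the log2 values carried 15.8%, 15.2% and 12.9% of the variance.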
